A study of Homo sapiens with 6 samples.

How the data were processed

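RNA was measured in LX-2 cells, an immortalised human hepatic stellate cell line, after 2 days with the aminopropyl carbazole P7C3 at 20 µM or after 2 days with no drug. Each group held 3 samples, so 6 libraries were compared. The labels name no solvent control, so the effect of P7C3 and that of its solvent were not separated. All 6 samples carry the same batch label. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which could be technical.

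Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a stranded, poly(A)-selecting mRNA kit. Per the submitters' processing notes, fastp and HISAT2 were used with genome build GRCh38, and neither has a version given in the sources used here. The name of the deposited table carries the words RSEM and TPM, and no other source used here says how transcripts were quantified or which annotation release was used. The authors deposited TPM (transcript abundance as a share of a fixed total) with 1 column per library, 63241 genes and values written to 2 decimals. Of these genes, 20601 had no symbol. Each column summed to between 999999 and 1000001 TPM. TPM keeps no sequencing depth, so the depth of the libraries is unknown and no counting interval or detection floor could be given. Because TPM is a share of a fixed total, a rise of some genes lowers the share left for the others.

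TPM was converted to log2(TPM + 1), with a pseudocount of 1, which understates the change of genes with low values. Genes with a TPM of at least 1 in at least 3 libraries were tested, 15224 in all. P7C3 and untreated libraries were compared with limma 3.58.1 in R 4.3.3, with the prior variance following mean expression (trend) and no replicate block. P-values were two-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. Of the 48 gene lists written before the data were examined, the 44 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera asks whether the members of a list moved more than the other genes, and it was repeated with the correlation estimated for each list. A second list test set beforehand, limma's fry, asks whether the members moved in a common direction, without comparing them with the other genes. Its p-values were adjusted over the lists. Genes named in or implied by the series title, 26 in all, were also adjusted over that list alone. Measures of single libraries were compared with two-sided exact permutation tests, which cannot go below p = 0.1 for 3 against 3.

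The genes named were set by a rule fixed before the data were examined. It takes the tested genes of the title's list, the 8 raised and 8 lowered genes with the largest change among those past the threshold, with no overlap between groups and a mean of at least 10 TPM in the higher group, up to 4 members of each gene list past the threshold with at least 5 TPM in the higher group, and the 3 most abundant genes of each group. Where fewer than 2 members of a list passed, its most abundant member was taken with its values. Genes named outside the rule are said to be so, and not every gene that met the rule is named. Transcript lengths and gene positions came from GENCODE 29 (GRCh38), with the length of the transcript that has the longest coding sequence. Of the tested genes, 95.8% had a length.

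The scripts were tested on simulated data for the comparison of P7C3 with untreated cells, with 15224 genes of which 200 were changed. Of genes changed 2-fold, 58% were recovered, and of genes changed 4-fold, 91%. Unchanged genes made up 1.32% of the calls. The simulated genes were drawn independently, with the same spread in both groups and no trend shared by the genes of a library. These shares need not hold for the real libraries.

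The alternatives fixed before the data were examined changed the filter on low values, the pseudocount, the scaling between libraries, the variance model, the gene classes, the libraries included and, for the lists, the correlation and the statistic. Alternatives added afterwards removed a trend of expression on transcript length or GC content, weighted the libraries, combined median centring with leaving out P7C3 replicate 3, and repeated the fits that leave out 1 library with a filter that asks for 2 libraries in place of 3. The last was added because a gene near 0 in untreated cells cannot pass a filter of 3 libraries once a P7C3 library is left out, which removed GDF15, CXCL3 and SPP1 from each fit without a P7C3 library. Pathways from the KEGG column of the deposited table were also tested after the data were examined. Alternatives that need read counts were not run. Histones, metallothioneins, actins, tubulins and mitochondrial genes hold close copies or overlapping genes, so how reads were divided among them is uncertain.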

Results

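The series compared gene expression in LX-2 cells treated with P7C3, a small molecule known as a neuroprotective compound, with that in untreated cells. LX-2 is a line of hepatic stellate cells, the cells that lay down scar matrix in the injured liver. The series title names the RNA helicase eIF4A1, protein translation, autophagy and hepatic fibrosis, so the comparison asks what 2 days with 20 µM P7C3 did to the transcripts of these cells. Each group held 3 libraries, and expression was given as TPM at unknown depth. Each untreated library had 14881 to 14982 genes with at least 1 TPM, and the P7C3 libraries had 15338, 15201 and 15686. Long non-coding RNA took 2.06 ± 0.016% of the TPM in untreated and 2.45 ± 0.010% in P7C3 libraries. Mitochondrial rRNA took 0.293 ± 0.013% and 0.441 ± 0.062%. These measures each gave an exact permutation p of 0.1, the smallest possible. The share of mitochondrial mRNA, 7.08 ± 0.18% and 5.91 ± 1.22%, gave 0.2. The cause was not tested. The most abundant transcripts were MT-ATP8, TMSB10 and MT-ND4L in untreated cells, and MT-ATP8, EEF1A1 and MT-ND4L with P7C3.

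The collagenase MMP1 rose. The lists of the integrated and endoplasmic reticulum stress responses, of the lysosome and of inflammatory and interferon genes lay above the other genes with P7C3. Those of the contractile myofibroblast, cholesterol synthesis and cell division lay below the other genes. These list calls are camera's at a preset correlation, and with an estimated correlation 0 lists were called. Of 15224 tested genes, 2724 changed (limma, adjusted p under 0.05), with 2127 raised and 597 lowered, and 658 of them changed at least 2-fold. The median gene lay 0.19 higher on the log2 scale with P7C3, and 78.1% of the changed genes were raised. After median centring, 3330 genes changed, with 1402 raised and 1928 lowered, so that 42.1% were raised. Both fits shared 1402 raised and 596 lowered genes. Whether more genes rose or fell therefore depended on the scaling. In 43.3% of the tested genes the groups did not overlap in TPM, where chance gives 10%. Of the tested genes, 5059 were higher and 1534 lower in every P7C3 library. The median log2(TPM + 1) was 3.97 to 4.02 in untreated and 4.11 to 4.43 in P7C3 libraries. A shift in scaling could thus add to this share, which was not computed after median centring. Without untreated replicate 1, 2 or 3 the count of changed genes was 987, 1110 or 956, and without P7C3 replicate 1 or 2 it was 1416 or 3174.

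**Figure D1:**
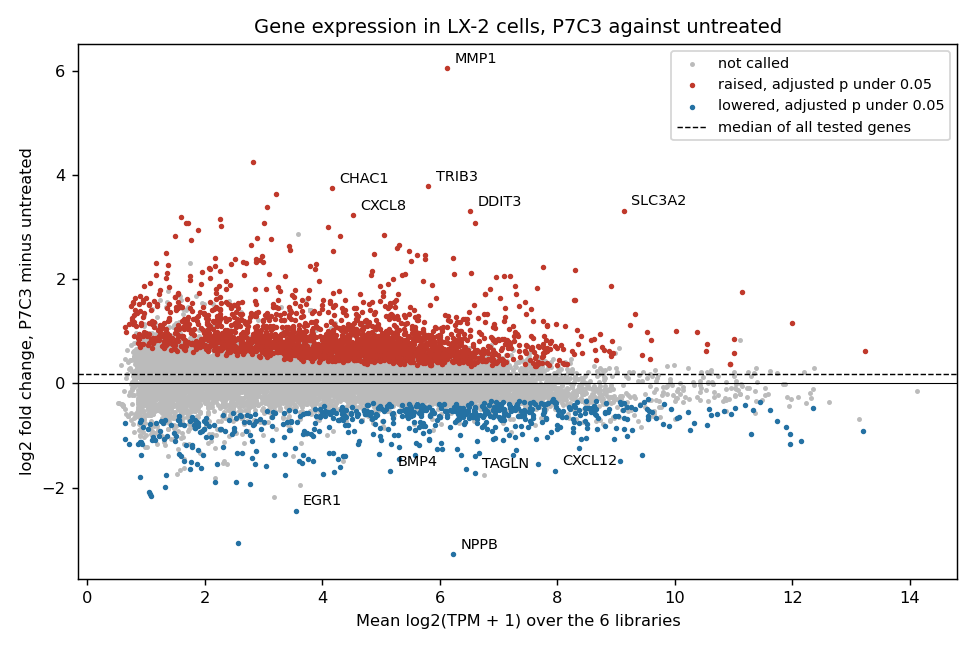
Change of each tested gene (vertical axis, log2 fold change of P7C3 minus untreated on the log2(TPM + 1) scale) against its mean log2(TPM + 1) over the 6 libraries (horizontal axis). Red points are the 2127 raised genes, blue points the 597 lowered genes, grey points genes not called, and the dashed line the median of all tested genes at 0.19. MMP1 stands at the top with a log2 change of 6.05 and NPPB at the bottom with -3.28.

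P7C3 replicate 3 stood apart from the other libraries. Its correlation with P7C3 replicates 1 and 2 was 0.970 and 0.964, against 0.983 between those libraries and 0.981 to 0.984 among untreated libraries (across genes, which are not independent replicates). Its expression rose with transcript length. The median gene lay 0.0098 above the untreated mean for transcripts under 1000 nt and 0.543 above it for those over 6000 nt, where P7C3 replicate 1 lay between 0.074 and 0.153 in every length class and P7C3 replicate 2 between 0.031 and 0.097. Without P7C3 replicate 3, 3868 genes changed, with 2518 raised (65.1%) and 1350 lowered, and 1932 raised and 582 lowered genes were shared with the fit on all libraries.

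**Figure D2:**
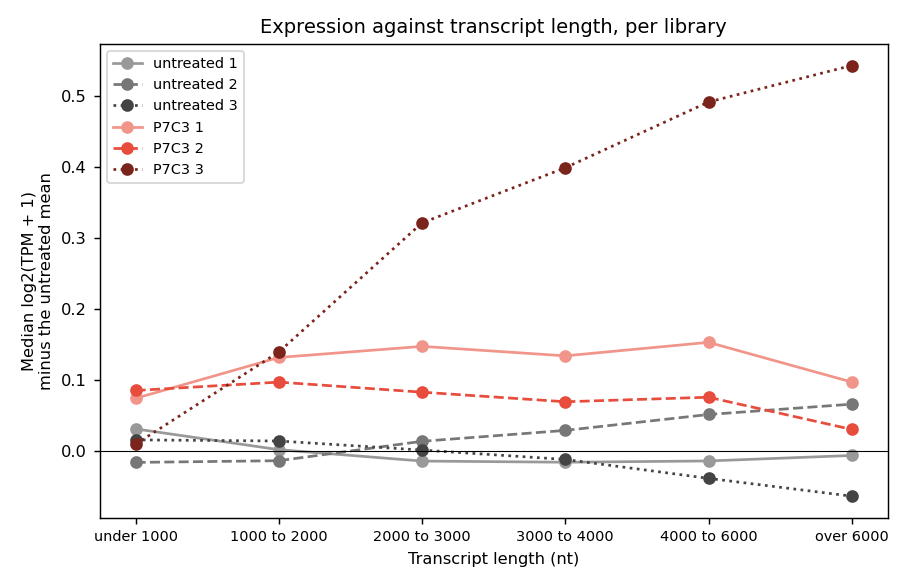
Median over genes of log2(TPM + 1) minus the untreated mean (vertical axis) in 6 classes of transcript length in nt (horizontal axis), with a line for each library. P7C3 replicate 3 climbs from 0.0098 to 0.543 with length, and the other P7C3 libraries stay between 0.031 and 0.153.

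The largest rise among the genes named by the fixed rule was that of MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160, minus strand, GRCh38), an interstitial collagenase. It stood at 7.62 ± 1.23 TPM in untreated cells and 575 ± 116 TPM with P7C3 (SD, n = 3), a log2 change of 6.05 ± 0.17 (SE, adjusted p = 3.64e-06). TRIB3, CHAC1, NUPR1, LURAP1L, SLC3A2, DDIT3 and CXCL8 followed, with log2 changes from 3.79 to 3.23. The largest fall was that of NPPB (ENSG00000120937, chromosome 1, 11857464 to 11858931, minus strand), which encodes brain natriuretic peptide, from 233 ± 15.3 to 24.2 ± 8.83 TPM, a log2 change of -3.28 ± 0.25 (adjusted p = 0.000252). EGR1, CORO1A, SAMD11, MGARP, TAGLN, BMP4 and CXCL12 followed, with log2 changes from -2.45 to -1.68. CXCL12, a chemokine made by stellate cells, went from 447 ± 2.03 to 139 ± 9.36 TPM.

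Of the 44 lists tested, 30 were called by camera, with 12 lying above and 18 below the other genes. Some lists share members, so their calls are not independent. Also in another fixed list were 7 of 35 tested ATF4 targets, 8 of 26 p53 targets and 6 of 26 NF-kB genes. The same held for 4 of 25 NRF2 targets and 13 of 20 senescence genes. With an estimated correlation 0 lists were called, and the smallest adjusted p was 0.0838, so a list call alone is weak evidence. That estimate rests on only 6 libraries. Even the ATF4 list, with 34 of 35 members raised, had adjusted p = 0.36 with it. A missing call with an estimated correlation is therefore not evidence that a list did not move. When the groups were mixed, camera at its preset correlation still called 10 to 22 lists with at most 5 genes changed. Each mixed split kept part of the treatment contrast, so its list calls do not measure how often camera calls falsely. Fry did not call the lists of oxidative phosphorylation, S phase, hypoxia and TGF-beta response (adjusted p = 0.17, 0.246, 0.115 and 0.0514). Nor did it call the mitochondrially encoded, collagen and matrix glycoprotein lists (0.281, 0.529 and 0.398). The ribosomal protein, growth factor, heat shock and fatty acid synthesis lists each had adjusted p = 0.875. Fry called the other lists that camera called, and some that camera did not, such as the senescence list (0.00253). These values test for a common direction. Fry's mixed test lets members move either way. Of the lists camera called, it missed only oxidative phosphorylation and the cytosolic ribosomal proteins (adjusted p = 0.137 and 0.429). The counts of changed members given for each list are over all tested genes, and the p-values of lists are camera's unless said otherwise.

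The integrated stress response list had the highest median of the tested lists. Of 35 tested genes of the ATF4 list, the targets of the integrated stress response, 34 rose over all genes and 34 adjusted over the list alone, with a median log2 change of 2.06 (adjusted p = 2.71e-28, and adjusted p = 0.36 with an estimated correlation). DDIT3, the stress-induced factor CHOP (chromosome 12, 57516588 to 57521737, minus strand), went from 28.2 ± 1.16 to 287 ± 14.3 TPM. SLC3A2, the heavy chain of amino acid exchangers, went from 177 ± 5.39 to 1791 ± 273 TPM, and TRIB3 from 14.1 ± 0.987 to 209 ± 42.2 TPM. Of 22 cytosolic aminoacyl-tRNA synthetases, 12 rose and 0 fell (13 rose adjusted over the list alone), led by AARS1 from 79.7 ± 1.74 to 301 ± 72.3 TPM (list adjusted p = 0.000258, and adjusted p = 0.602 with an estimated correlation). Of 33 genes of the endoplasmic reticulum unfolded protein response, 23 rose and 0 fell (25 adjusted over the list alone, and 18 after median centring). HSPA5, the chaperone BiP, went from 252 ± 9.21 to 946 ± 266 TPM and XBP1 from 31.7 ± 2.30 to 173 ± 22.3 TPM. For this list, adjusted p = 1.1e-07, and adjusted p = 0.467 with an estimated correlation.

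**Figure D3:**
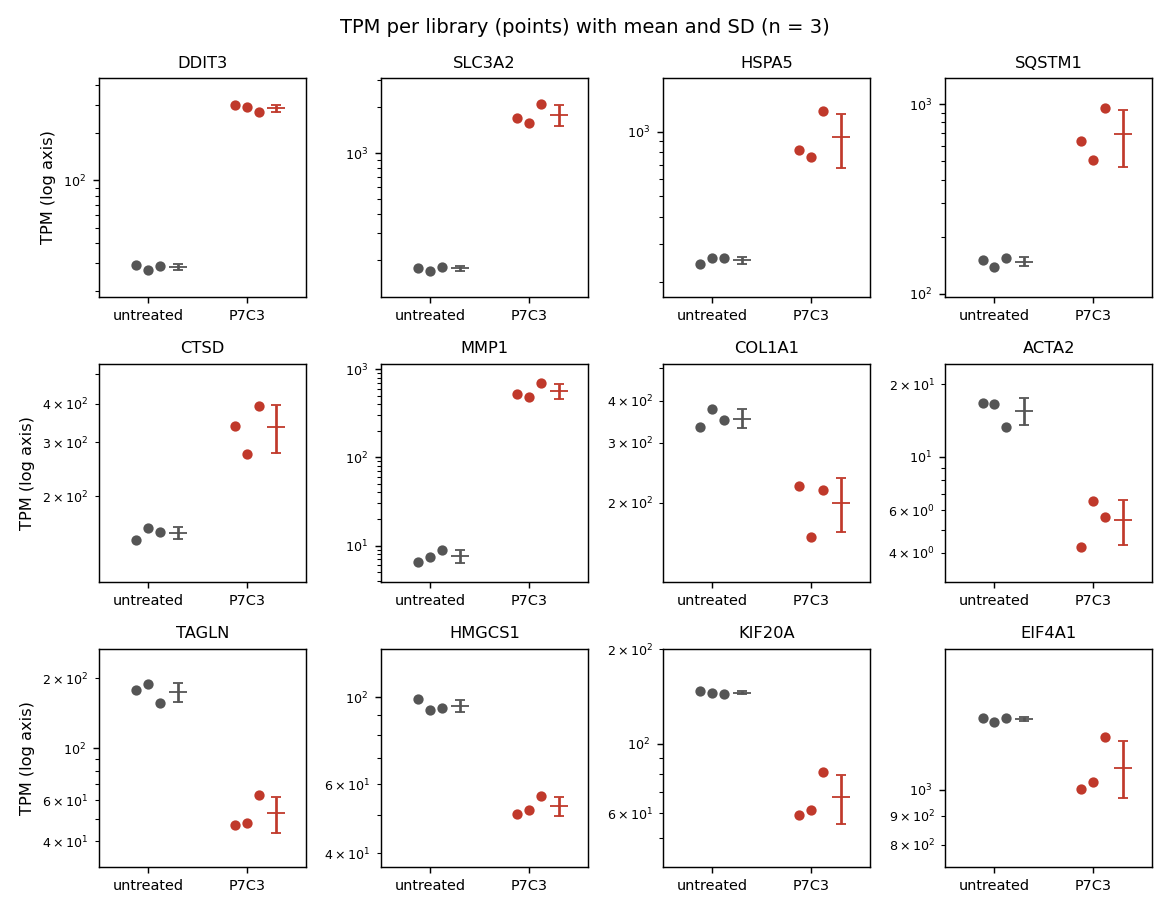
TPM of 12 named genes in each library (points, log axis) with the mean and SD of each group (n = 3) beside them. DDIT3 stands at 28.2 TPM in untreated cells and 287 TPM with P7C3, ACTA2 at 15.5 and 5.47 TPM, and EIF4A1 at 1335 and 1093 TPM.

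The lysosomal and autophagy lists were called as higher. Of 49 lysosomal genes, 28 rose and 1 fell (38 and 1 adjusted over the list alone, and 20 and 1 after median centring). CTSD, a lysosomal protease, went from 152 ± 6.82 to 335 ± 59.5 TPM and NEU1 from 17.3 ± 1.00 to 54.1 ± 9.91 TPM. The list's adjusted p was 3.13e-08, and adjusted p = 0.565 with an estimated correlation. Of 49 core autophagy genes, 12 rose, 1 fell and 36 were not called (15 rose and 1 fell adjusted over the list alone, and 6 rose and 1 fell after median centring). The receptor SQSTM1 went from 148 ± 8.56 to 698 ± 230 TPM, a log2 change of 2.18 ± 0.21, and MAP1LC3B from 26.8 ± 0.816 to 51.5 ± 3.20 TPM, with GABARAPL1 and WIPI1 also raised (list adjusted p = 0.00665, and adjusted p = 0.676 with an estimated correlation). SQSTM1 is also a target of ATF4 and NRF2. Of 29 mTORC1 pathway genes, 8 rose and 0 fell (8 adjusted over the list alone) and the list was not called (adjusted p = 0.135), and SESN2 went from 6.41 ± 0.242 to 53.3 ± 15.4 TPM.

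Of the 25 tested genes taken from the title, 12 changed over all genes (8 raised, 4 lowered) and 13 adjusted over the list alone (9 raised, 4 lowered). EIF4A1 itself (chromosome 17, 7572706 to 7579005, plus strand) stood at 1335 ± 11.9 TPM in untreated cells and 1093 ± 127 TPM with P7C3, a log2 change of -0.29 ± 0.11 that was not called over all genes (adjusted p = 0.101) or over the list alone (adjusted p = 0.0502). It was called after median centring (adjusted p = 0.0132) and without P7C3 replicate 3 (adjusted p = 0.00117). Over its 27 alternatives the adjusted p ran from 5.11e-05 to 0.481, and 7 called it. These include the library weights, whose estimation did not converge, and several overlapping fits without P7C3 replicate 3. The translation repressor PDCD4 rose from 23.8 ± 0.369 to 41.8 ± 5.35 TPM (adjusted p = 0.00589). ULK1, LAMP1, NAMPT, MYC and CCND1 also rose, with log2 changes from 0.33 to 1.27, and those of LAMP1 and CCND1 were not called after median centring (adjusted p = 0.292 and 0.589). EIF4A2, EIF4E, EIF4G1, FN1, TIMP1, TGFB1, PDGFRB, ATG5, ATG7, TFEB and MTOR were not called, with adjusted p from 0.124 to 0.95. Of these, EIF4E and EIF4G1 were called as lower after median centring (adjusted p = 0.00535 and 0.00351) and without P7C3 replicate 3 (0.0104 and 0.00226), and TGFB1 as lower after median centring (0.0159). Without P7C3 replicate 3, FN1 was called as lower and TIMP1 as higher (0.00287 and 0.00356). BECN1 was called over the list alone (adjusted p = 0.0212 there and 0.0568 over all genes) and over all genes without P7C3 replicate 3 (0.0199). COL1A2 was not tested, with 0.18 to 0.66 TPM.

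The contractile list and several matrix genes were lower. Of 17 contractile myofibroblast genes, 10 fell and 0 rose (11 adjusted over the list alone), with a median log2 change of -0.56 (adjusted p = 1.77e-12, and adjusted p = 0.109 with an estimated correlation). ACTA2, which encodes alpha-smooth muscle actin (chromosome 10, 88935074 to 88991339, minus strand), went from 15.5 ± 1.92 to 5.47 ± 1.16 TPM, and TAGLN from 175 ± 16.4 to 52.6 ± 9.13 TPM. Of 13 collagen genes, 3 fell and 1 rose (3 and 2 adjusted over the list alone, 7 and 1 after median centring, 6 and 1 without P7C3 replicate 3). COL1A1 (chromosome 17, 50183289 to 50201632, minus strand) went from 354 ± 23.0 to 200 ± 35.8 TPM, with COL3A1 and COL18A1 also lowered. COL6A3 rose from 60.6 ± 3.76 to 108 ± 17.6 TPM (list adjusted p = 0.0203, adjusted p = 0.676 with an estimated correlation, and adjusted p = 0.121 without P7C3 replicate 2). Of 18 matrix glycoproteins and proteoglycans, 5 fell and 1 rose (5 and 4 adjusted over the list alone, 7 and 0 after median centring, 9 and 3 without P7C3 replicate 3), with FSTL1 from 506 ± 24.8 to 219 ± 54.5 TPM and THBS1 from 59.8 ± 3.74 to 25.3 ± 5.50 TPM (adjusted p = 0.00358, and adjusted p = 0.661 with an estimated correlation). Of 18 genes of collagen processing, 6 rose and 0 fell (7 adjusted over the list alone, and 3 and 3 after median centring), FKBP10 among them, and the list was not called (adjusted p = 0.508). Of 18 matrix proteases and inhibitors, 6 rose and 2 fell (6 and 2 adjusted over the list alone), MMP1, SERPINE2, PLAU and MMP14 among those raised (list adjusted p = 0.183).

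Signalling lists tied to the myofibroblast were called as lower. Of 24 TGF-beta response genes, 7 fell and 3 rose (9 and 4 adjusted over the list alone, 11 and 2 after median centring, 9 and 4 without P7C3 replicate 3), with SMAD6, ID3, ID2 and ID1, which are targets of BMP signalling, among those lowered (adjusted p = 0.000258, and adjusted p = 0.467 with an estimated correlation). Of 24 YAP and SRF targets, 7 fell and 1 rose (8 and 1 adjusted over the list alone, 15 and 0 after median centring, 15 and 1 without P7C3 replicate 3), with CCN1 from 552 ± 9.35 to 300.1 ± 10.9 TPM (adjusted p = 1.54e-08, and adjusted p = 0.467 with an estimated correlation). Of 32 growth factors and receptors, 6 fell and 4 rose (6 and 4 adjusted over the list alone, 9 and 3 after median centring, 8 and 5 without P7C3 replicate 3). VEGFA rose by 2.66 on the log2 scale and IGFBP3 fell. The list's median of 0.01 and its mean of 0.00083 were above 0 while camera placed it below the other genes (adjusted p = 0.0149, adjusted p = 0.59 with an estimated correlation, 0.115 with no low-value filter and 0.081 with a filter of at least 5 TPM). Of 15 genes of the quiescent stellate cell, 6 rose and 2 fell (9 and 2 adjusted over the list alone), PLIN2, a lipid droplet protein, among those raised. This list had adjusted p = 0.0372 and adjusted p = 0.567 with an estimated correlation. With the filter at 3 libraries it was not called without any single P7C3 library (adjusted p = 0.0621, 0.161 and 0.149 without replicates 1, 2 and 3).

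The cholesterol synthesis list was called as lower. Of 26 genes, 12 fell and 0 rose (17 adjusted over the list alone, 23 after median centring and 19 without P7C3 replicate 3), with a median log2 change of -0.43 (adjusted p = 2.03e-15, and adjusted p = 0.442 with an estimated correlation). HMGCS1, an early enzyme of the pathway (chromosome 5, 43289395 to 43313512, minus strand), went from 95.1 ± 3.33 to 52.7 ± 3.01 TPM. Of 8 LXR targets and sterol efflux genes, 4 rose and 0 fell (5 adjusted over the list alone and 2 after median centring), with the cholesterol exporter ABCA1 from 2.54 ± 0.349 to 17.3 ± 5.28 TPM (adjusted p = 0.0266, adjusted p = 0.567 with an estimated correlation, and adjusted p = 0.0904 without P7C3 replicate 1). Of 19 fatty acid synthesis genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone, 1 and 10 after median centring, 2 and 4 without P7C3 replicate 3), with SCD lowered and SREBF1 and ELOVL6 raised. The list's adjusted p was 0.028, and adjusted p = 0.715 with an estimated correlation. It was not called without untreated replicate 1, P7C3 replicate 1 or P7C3 replicate 2 (adjusted p = 0.0543, 0.0958 and 0.1). Of 24 fatty acid oxidation genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 1 and 6 after median centring, 2 and 3 without P7C3 replicate 3), with UCP2 from 101 ± 6.56 to 41.6 ± 1.52 TPM (list adjusted p = 0.3).

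The lists of cell division were called as lower. Of 54 G2 and M phase genes, 23 fell, 0 rose and 31 were not called (30 fell adjusted over the list alone, 46 after median centring and 40 without P7C3 replicate 3), with KIF20A, a mitotic kinesin, from 146 ± 1.45 to 67.4 ± 12.1 TPM and ANLN from 206 ± 5.50 to 117 ± 18.8 TPM. The test gave adjusted p = 1.69e-21, and adjusted p = 0.46 with an estimated correlation. Of 45 S phase genes, 8 fell, 1 rose and 36 were not called (8 fell and 1 rose adjusted over the list alone, 22 and 0 after median centring, 20 and 1 without P7C3 replicate 3), with RRM2 from 274 ± 17.5 to 165 ± 18.9 TPM (adjusted p = 1.39e-06, and adjusted p = 0.567 with an estimated correlation). Of 31 replication-dependent histones, whose transcripts are mostly short and not polyadenylated, 8 fell and 0 rose (11 adjusted over the list alone; list adjusted p = 7.65e-09, and adjusted p = 0.0838 with an estimated correlation). After median centring 11 histones fell, and without P7C3 replicate 3, 9 fell. H2BC11 went from 41.6 ± 1.20 to 22.5 ± 2.53 TPM. The libraries were poly(A)-selected, so these values may not stand for histone transcripts as a whole. Of 26 p53 targets, 9 rose and 0 fell (10 adjusted over the list alone, and 6 and 2 after median centring), with PMAIP1 from 19.5 ± 0.971 to 87.6 ± 4.41 TPM. The p53 list had adjusted p = 0.0203 and adjusted p = 0.567 with an estimated correlation. It was not called after median centring, without P7C3 replicate 2 or without P7C3 replicate 3 (adjusted p = 0.0511, 0.117 and 0.0636). Of 28 apoptosis regulators, 6 rose and 1 fell (9 and 3 adjusted over the list alone, and 6 and 4 after median centring; list adjusted p = 0.347), and of 20 genes of the senescence list 7 rose and 5 fell (10 and 6 adjusted over the list alone; list adjusted p = 0.897).

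The inflammatory and interferon lists were called as higher. Of 26 NF-kB genes, 14 rose and 0 fell (16 adjusted over the list alone), with the chemokine CXCL8 from 6.55 ± 0.435 to 69.8 ± 6.11 TPM and IL1B from 6.60 ± 1.18 to 43.3 ± 7.09 TPM (adjusted p = 1.38e-06, and adjusted p = 0.467 with an estimated correlation). Of 41 interferon response genes, 25 rose and 0 fell (30 and 1 adjusted over the list alone, and 19 and 1 after median centring). IFIT2 went from 3.34 ± 0.363 to 26.4 ± 5.34 TPM (list adjusted p = 6.06e-08, and adjusted p = 0.442 with an estimated correlation). Of 25 immediate early genes, 11 rose and 1 fell (14 and 3 adjusted over the list alone, and 9 and 4 after median centring), with KLF4 and ATF3 raised (list adjusted p = 0.185).

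Of 25 NRF2 targets, which act against oxidants, 10 rose and 1 fell (12 and 1 adjusted over the list alone), with the cystine transporter SLC7A11 from 5.04 ± 0.356 to 47.7 ± 7.58 TPM, HMOX1 from 25.7 ± 2.40 to 103 ± 14.2 TPM and the ferritin light chain FTL from 1233 ± 25.3 to 4197 ± 263 TPM (adjusted p = 0.00665, and adjusted p = 0.567 with an estimated correlation). Of 7 metallothionein and zinc genes, 4 rose and 0 fell (7 adjusted over the list alone, 1 after median centring and 7 without P7C3 replicate 3), with SLC30A1, a zinc exporter, from 14.1 ± 1.09 to 26.5 ± 1.98 TPM (adjusted p = 0.00354, and adjusted p = 0.442 with an estimated correlation). MT1F, MT1X and MT1E, which lay lower in P7C3 replicate 3 than in the other P7C3 libraries, were not called after median centring (adjusted p = 0.0603, 0.0875 and 0.105). Of 34 hypoxia and glycolysis genes, 12 fell and 5 rose (12 and 5 adjusted over the list alone, 18 and 5 after median centring, 16 and 5 without P7C3 replicate 3), with LDHA, lactate dehydrogenase A, from 899 ± 23.0 to 320.5 ± 23.1 TPM and ADM from 75.5 ± 2.96 to 28.6 ± 2.24 TPM (adjusted p = 2.11e-06, and adjusted p = 0.567 with an estimated correlation). Of 23 heat shock genes, 1 rose (HSPA9) and 1 fell (HSPB1), over all genes and adjusted over the list alone. After median centring 1 rose and 9 fell, and without P7C3 replicate 3, 1 rose and 8 fell. The heat shock list had adjusted p = 0.0266, and adjusted p = 0.676 with an estimated correlation. It was not called in further alternatives (adjusted p = 0.549 after quantile normalization, and adjusted p = 0.114 and 0.0766 without P7C3 replicates 1 and 2).

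Several lists of shorter transcripts were called as lower. In P7C3 replicate 3 expression rose with transcript length. With that library, the oxidative phosphorylation, mitochondrially encoded and mitochondrial ribosomal protein lists had lower medians than without it. The proteasome list's median log2 change was -0.20 with it and -0.19 without it, or -0.39 and -0.29 relative to all genes. Of 76 nuclear-encoded oxidative phosphorylation genes, 3 fell (ATP5MF, ATP5F1D and ATP5MC1) and 0 rose, with 0 and 0 adjusted over the list alone. After median centring 12 fell, and without P7C3 replicate 3, 20 fell and 1 rose. The list's median log2 change was -0.33, and -0.16 without P7C3 replicate 3 (adjusted p = 2.03e-15, and adjusted p = 0.467 with an estimated correlation). Of 36 proteasome genes, 3 fell and 0 rose (0 and 0 adjusted over the list alone), while 17 fell after median centring and 19 without P7C3 replicate 3, with PSMA2 from 116 ± 8.61 to 75.1 ± 16.3 TPM (adjusted p = 1.73e-09, and adjusted p = 0.0838 with an estimated correlation). Of 13 mitochondrially encoded transcripts, 2 fell and 1 rose (3 and 1 adjusted over the list alone, 2 and 0 after median centring, 5 and 3 without P7C3 replicate 3), with MT-CO2 from 6693 ± 282 to 3161 ± 773 TPM (adjusted p = 0.00067, adjusted p = 0.567 with an estimated correlation, and adjusted p = 0.0534 after median centring and 0.0888 without P7C3 replicate 3). Of 76 mitochondrial ribosomal proteins, 3 rose and 2 fell (1 and 1 adjusted over the list alone, 1 and 3 after median centring, 10 and 8 without P7C3 replicate 3; list adjusted p = 0.00171, adjusted p = 0.567 with an estimated correlation, and adjusted p = 0.293 without P7C3 replicate 3).

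The cytosolic ribosomal proteins depended on P7C3 replicate 3 for their direction. Of 79 genes, 1 rose (RPL4) and 0 fell over all genes, and 0 rose and 0 fell adjusted over the list alone. Camera placed the list below the other genes (adjusted p = 0.00067, and adjusted p = 0.716 with an estimated correlation). Without P7C3 replicate 3, 28 rose and 3 fell and the list lay above the other genes (adjusted p = 0.00233). Over its 29 alternatives the adjusted p ran from 1.79e-09 to 0.96. They took 15.4%, 14.9% and 15.4% of the TPM of the untreated libraries, 16.2% and 16.98% in P7C3 replicates 1 and 2 and 11.2% in P7C3 replicate 3.

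Of 45 translation initiation factors, 7 rose and 1 fell (8 and 1 adjusted over the list alone, 4 and 11 after median centring, 12 and 8 without P7C3 replicate 3), with EIF4EBP1, a repressor of cap-dependent initiation and an ATF4 target, from 171 ± 16.4 to 377 ± 47.4 TPM and EIF2S2 from 148 ± 2.64 to 235 ± 5.13 TPM (list adjusted p = 0.897). Of 17 elongation and release factors, 3 rose and 0 fell (3 adjusted over the list alone, 1 and 2 after median centring, 5 and 1 without P7C3 replicate 3), with EEF1A1 from 7776 ± 44.8 to 12021 ± 1143 TPM, not called after median centring (adjusted p = 0.249; list adjusted p = 0.708). Of 48 ribosome biogenesis genes, 2 rose and 1 fell, with 0 and 0 adjusted over the list alone (list adjusted p = 0.185). After median centring 2 rose and 9 fell and the list was called as lower (adjusted p = 0.0301), and without P7C3 replicate 3, 3 rose and 7 fell.

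Of 24 genes of NAD salvage and use, 7 rose and 0 fell (7 adjusted over the list alone, and 3 and 4 after median centring), with NAMPT, the rate-limiting enzyme of NAD salvage, from 49.0 ± 1.06 to 121 ± 26.6 TPM (adjusted p = 0.00176 for the gene and 0.185 for the list). Of 6 aryl hydrocarbon receptor targets, 3 rose and 0 fell (3 adjusted over the list alone; list adjusted p = 0.131), CYP1A1 and NQO1 among them, and of 13 xenobiotic metabolism genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.722).

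Markers of other liver cells were mostly under the filter. Of 7 tested cholangiocyte markers, 3 rose and 2 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.276), with KRT8 and KRT18 lowered and SPP1 and SOX9 raised, and the list was called as lower without P7C3 replicate 1 or 2 (adjusted p = 0.0362 and 0.0393), where the filter at 3 libraries left out SPP1. With the filter at 2 libraries, which keeps SPP1, the cholangiocyte markers were not called (adjusted p = 0.258 and 0.223). Lists with fewer than 5 tested members were not tested as lists. The hepatocyte list had 4 tested members and 0 changed, with CPS1 at 9.13 ± 0.333 and 13.0 ± 5.74 TPM. The macrophage list had 2, with CD68, also a lysosomal protein, at 46.3 ± 0.961 and 86.8 ± 24.2 TPM and 1 member raised. The endothelial list had 3, with TIE1 at 31.4 ± 3.17 and 54.6 ± 11.8 TPM and 2 members raised, and the lymphocyte list had 3 with 0 changed and IL7R at 85.1 ± 4.45 and 75.7 ± 13.3 TPM.

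**Figure D4:**
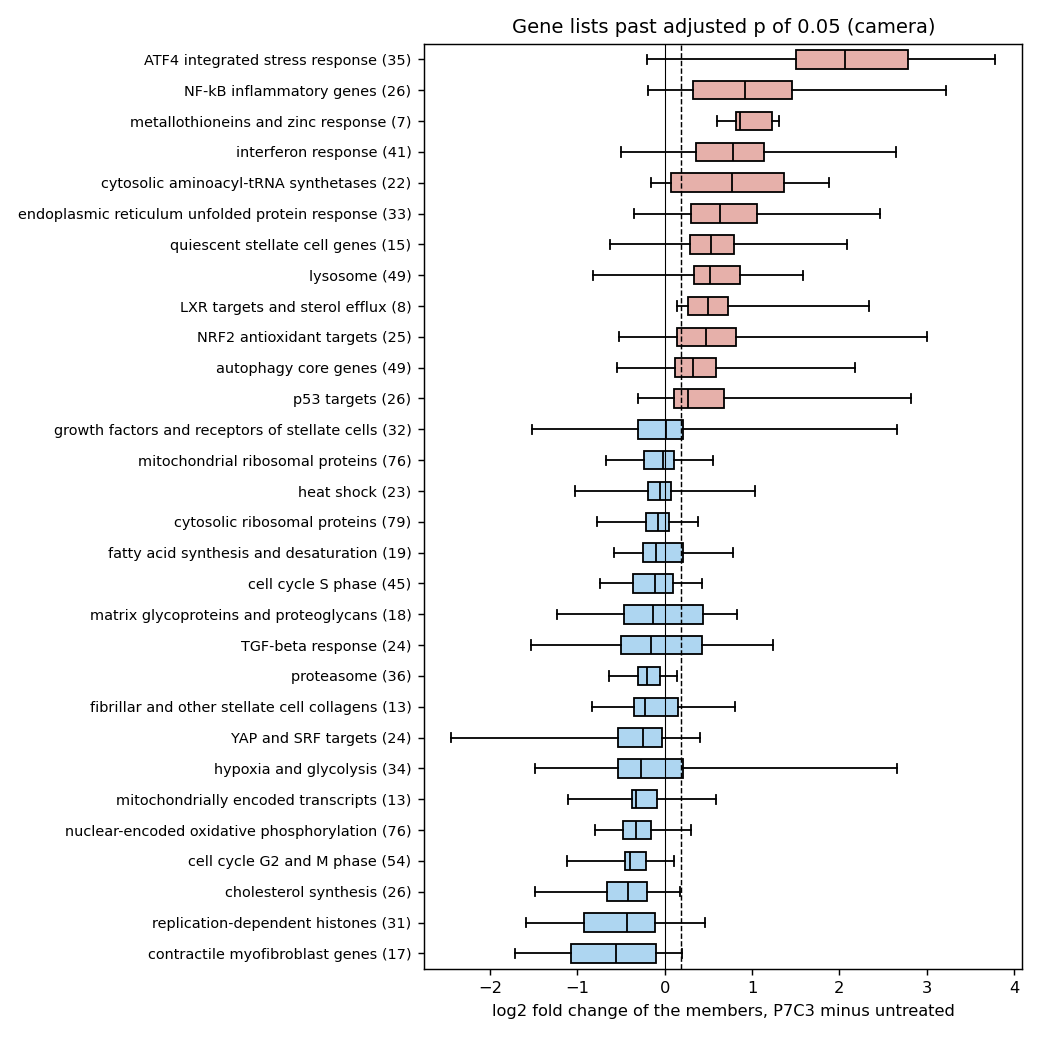
Log2 fold changes of the tested members of the 30 called lists (horizontal axis, P7C3 minus untreated), with boxes for the quartiles, a line for the median, whiskers to the extremes and the number of members in parentheses. Red lists lay above and blue lists below the other genes by camera, the dashed line marks the median of all genes at 0.19, and the ATF4 list has the highest median at 2.06.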

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

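The trend removals, the library weights, the combination of median centring with leaving out P7C3 replicate 3 and the 2-library filter were chosen after the data were examined. Alternatives that need read counts were not run, since the values were TPM, and the unknown depth limits what can be said of genes with low values. The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. Of these splits, 1, the real one, gave as many genes changed (2724, highest other 5), raised (2127, highest other 3), lowered (597, highest other 3) or changed at least 2-fold (658, highest other 5), as many title genes (13, highest other 0) and as many lists (30, highest other 22). The other splits called between 10 and 22 lists with at most 5 genes changed, so camera with its preset correlation called many lists where the groups mixed both treatments. With the correlation estimated per list, 0 were called.

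The counts moved with the filter, the scaling and the libraries. With no low-value filter, which took the genes tested to 30875, 1344 genes changed, 1009 raised and 335 lowered. With a pseudocount of 5, 293 changed at least 2-fold. Lowered genes came to 1928 after median centring, when 1402 were raised, to 1309 after quantile normalization, to 1940 with the length trend and 1696 with the GC trend removed, and to 2511 after median centring with P7C3 replicate 3 left out, when 20 title genes changed. Library weights gave 8652 changed, 6056 raised, 2596 lowered and 21 title genes, but their estimation did not converge and gave P7C3 replicate 1 a weight of 15.8 and P7C3 replicate 3 a weight of 0.0988, so these values are not relied on. Ranges given over all alternatives of a gene or list include the fit with library weights. Replicate numbers did not pair the samples (correlations of -0.11, -0.0073 and -0.13 between same-numbered samples, and 0 of 3 correlated best with their own number), and the fit with a replicate block called 1979 genes, 1556 raised and 423 lowered. Apart from what the construction of each alternative shows, the cause was not tested.

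Leaving out 1 library at a time gave 956 to 3868 genes changed, 766 to 2560 raised, 190 to 1350 lowered, 480 to 787 changed at least 2-fold and 8 to 19 title genes. With the filter at 2 libraries these were 831 to 3859, 655 to 2560, 176 to 1299, 524 to 873 and 8 to 19. The lists called ranged from 26 to 30, and from 25 to 30.

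Directions turned for results that were not called, with 1 exception. The exception was the cytosolic ribosomal proteins, whose median relative to all genes was -0.27. It was 0.037 after quantile normalization and -0.046 with library weights, neither called, and ranged from -0.45 to 0.051 without 1 library, with the list called as higher without P7C3 replicate 3. Of the lists not called, camera's direction turned for initiation and elongation factors, from higher to lower, while their relative medians were already under 0 in the main fit (-0.00080 and -0.070) and stayed so where camera's direction turned. They were, for initiation factors, -0.00080 both after median centring and in limma without trend, -0.0049 in protein-coding genes, -0.0064 after rescaling without abundant genes, -0.022 with the length trend and -0.022 with the GC trend removed, -0.065 with library weights, -0.049 after median centring with P7C3 replicate 3 left out, and -0.053 to 0.021 without 1 library. For elongation factors they were -0.070 after median centring, -0.10 after rescaling, -0.053 with the length and -0.094 with the GC trend removed. Camera's direction also turned for the senescence list (relative median of 0.071 in the main fit, -0.20 with the stricter filter and -0.25 to 0.17 without 1 library) and xenobiotic metabolism (0.15 in the main fit, -0.14 with the stricter filter, 0.12 with library weights and -0.079 to 0.18 without 1 library). Among genes, log2 changes turned for ATG5 (0.21 in the main fit, -0.033 after median centring and -0.023 after quantile normalization), ATG7 (0.30 in the main fit, -0.016 after median centring with P7C3 replicate 3 left out), EIF4A2 (0.048 in the main fit, -0.20 after median centring, -0.19 with the length and -0.16 with the GC trend removed, -0.17 after median centring with P7C3 replicate 3 left out, and -0.018 to 0.091 without 1 library), FN1 (-0.12 in the main fit, 0.030 after quantile normalization and -0.41 to 0.054 without 1 library), TFEB (-0.019 in the main fit, 0.036 with library weights and -0.048 to 0.029 without 1 library), PDGFRB (-0.071 in the main fit, -0.35 to 0.19 without 1 library) and MT-ATP8 (-0.15 in the main fit, -0.22 to 6.2e-05 without 1 library).

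Calls of other lists also moved with the filter, the scaling and the statistic, all alternatives set before the data were examined. With no low-value filter the adjusted p was 0.163 for the collagens, 0.115 for fatty acid synthesis and for growth factors and 0.0914 for heat shock, none called, while the apoptosis (0.0448) and mTORC1 (0.0142) lists were called. With the filter at 5 TPM the quiescent stellate cell (0.234) and growth factor (0.081) lists lost their calls. Quantile normalization ended those of heat shock (0.549), the mitochondrially encoded transcripts (0.348) and p53 targets (0.0795), and gave one to immediate early genes (0.0451). Camera on ranks gave 0.0501 for the collagens and for p53 targets. The cause was not tested.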

Other observations

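Pathways of the KEGG column in the deposited table, tested after the data were examined, overlapped with the fixed lists to differing degrees. Of 317 pathways, 53 were called by camera at the preset correlation, 13 above and 40 below the other genes. With an estimated correlation none stayed called, and the smallest adjusted p was 0.0558. Of 44 genes of N-glycan biosynthesis, none of them in a fixed list, 10 rose and 0 fell, with DPAGT1, which starts the lipid-linked sugar chain, from 35.0 ± 1.65 to 63.6 ± 10.4 TPM and STT3A, a subunit of the enzyme that moves the chain to proteins, from 87.3 ± 6.00 to 164 ± 51.3 TPM (pathway adjusted p = 0.028, and adjusted p = 0.996 with an estimated correlation). Of 43 genes of amino sugar and nucleotide sugar metabolism, 5 of them in fixed lists, 15 rose and 0 fell, with GFPT1, which feeds the hexosamine pathway, from 30.6 ± 0.903 to 78.8 ± 23.3 TPM (adjusted p = 0.00838, and adjusted p = 0.996 with an estimated correlation). Of 37 sphingolipid metabolism genes, 9 of them in fixed lists, 13 rose and 0 fell, with HEXA among them (adjusted p = 0.00245, and adjusted p = 0.996 with an estimated correlation). Of 27 ferroptosis genes, 12 of them in fixed lists and SLC7A11, HMOX1 and FTL among these, 12 rose and 1 fell, with the ferritin heavy chain FTH1 from 2723 ± 28.7 to 6201 ± 1370 TPM (adjusted p = 0.00208, and adjusted p = 0.996 with an estimated correlation).

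Camera placed 2 pathways of the cytoskeleton below the other genes, while most of their members were not called. Of 112 motor protein genes, 15 of them in fixed lists, 27 fell and 10 rose, with a median log2 change of -0.049. Of 147 genes of actin cytoskeleton regulation, 14 of them in fixed lists, 22 fell and 12 rose, with a median of -0.0044 (adjusted p = 6.83e-06 and 0.000818, and adjusted p = 0.996 for both with an estimated correlation). ACTG1 went from 5610 ± 124 to 2877 ± 306 TPM, ACTB from 4386 ± 161 to 2667 ± 253 TPM and TUBB6 from 1319 ± 51.7 to 832 ± 61.9 TPM, and each fell with median centring and without P7C3 replicate 3 as well. The genes named in these paragraphs were chosen after their values were seen.

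In the paragraphs that follow, the tests of abundant transcripts and of GC content were set before their results were seen, and the other tests after. More genes rose than fell, and the median gene rose. If P7C3 replicate 3 alone gave this, the raised share should near 50% without it, and it was 65.1%. The median log2 change was 0.096 without it against 0.19 with it. That library raised the median but was not needed for the excess of raised genes at the scaling of the main fit. After median centring 42.1% of the changed genes were raised, and 36.6% with that library also left out, so the excess depended on the scaling. If a smaller share of the mitochondrial and 20 most abundant genes raised the median, leaving them out and rescaling the rest should undo it. The median change was 0.16 after that. Other abundant transcripts were kept in, so a smaller share of those stays open. A change in total RNA per cell, which TPM does not carry, stays open, as does a shift common to the P7C3 libraries.

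Several lists of shorter transcripts lay below the other genes, while the metallothionein list, with a median length of 1573 nt, lay above them. The NF-kB, ATF4 and lysosome lists (2281, 2656 and 2782 nt) also lay above them. The proteasome list, which lay below, had 2668.7 nt, and the median of all tested genes was 3288.5 nt. Lists with a median length under that of all genes thus lay on both sides. For the cytosolic and mitochondrial ribosomal proteins the data are consistent with a dependence on P7C3 replicate 3, since without it neither list was called as lower (adjusted p = 0.293 for the mitochondrial list, with the cytosolic list higher), yet transcript length as measured here is not the whole account, as both stayed lower after the length trend was removed (larger adjusted p = 0.0167). The oxidative phosphorylation, proteasome and histone lists stayed lower without that library (largest adjusted p = 1.72e-05), with the length trend removed (0.00092) and with the GC trend removed (9.4e-05), which argues against each as the whole cause. These p-values come from camera at its preset correlation, and with an estimated correlation none of these lists was called. What set P7C3 replicate 3 apart was not tested further.

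The cholesterol synthesis list lay below the other genes, and the list of LXR targets and sterol efflux lay above them. P7C3 replicate 3 or its length trend does not account for the former, which kept its call without either (larger adjusted p = 1.28e-13), though not with an estimated correlation (0.442). The call of the LXR list (adjusted p = 0.0266) was lost with an estimated correlation (0.567) and without P7C3 replicate 1 (0.0904), and over its 28 alternatives the adjusted p ran from 0.0058 to 0.567. What links the lists was not tested, and sterol levels were not measured here.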
